A study of Menidia beryllina with 24 samples.

How the data were processed

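Total RNA of whole inland silversides (Menidia beryllina) was measured on 24 custom 1-colour Agilent arrays, 1 array per sample. Per the labels, 200 ng of RNA per sample was labelled with Cy3 with the Low Input Quick Amp kit, and all labelling reactions were run at the same time. The labels put 6 samples in each of 4 groups: control, and nominal ibuprofen at 2.5, 0.25 and 0.025 mg/L, sampled after 14 d. Samples are named by group and replicate name as the labels give them. The labels do not say whether samples of a group shared a vessel or whether a sample was 1 fish, so the p-values measure only the spread between these samples.

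The scanner files hold the intensity of each spot as Feature Extraction 11.5.1.1 wrote it, per the file headers. The processed signal used here is an intensity that this software had corrected for background and for trends across the array, per the file headers. It had not been normalized between arrays. A deposited table of log2 values covers the same 24 arrays, and how its authors made it is not given in the sources used here. Those deposited log2 values were rebuilt from the scanner signals by setting a floor of 1, taking log2, quantile normalizing the arrays and subtracting the median of each probe. The rebuilt values lay within 0.01 of the deposited ones for 99.7% of all values, against 17.7% when the 75th percentile took the place of quantile normalization. The medians of its 24 columns lay between -0.10 and 0.03. The scale, centring and direction of that table were settled by this comparison, and the table was used as an alternative to the scanner signals.

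Each array held 43179 probes besides 1417 control spots, which were left out. The processed signal was taken to log2 and the 75th percentile of each array was subtracted, so a level of 0 is the 75th percentile of that array. Probes well above background on at least 6 of the 24 arrays, whatever their group, were tested, which left 34960 probes and removed 8219. A total of 26056 probes were well above background on all 24 arrays. Outlier flags for uneven spots marked between 2 and 36 probes per array and saturation flags at most 12, and those spots were kept.

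The groups were compared with limma 3.58.1 in R 4.3.3. A single linear model of the 4 group means was fitted to all 24 arrays, so that the groups shared 1 estimate of the spread of each probe, and empirical Bayes moderation was applied. The contrasts were each dose against control and each pair of doses. An F test covered the 3 contrasts with control, and a trend test used dose rank, with control as 0 and the doses as 1, 2 and 3. P-values were adjusted over the 34960 probes by the Benjamini-Hochberg method with a threshold of 0.05. The errors of log2 changes are standard errors from limma, and intervals have 95% confidence. For values of 1 measure per array, two-sided exact permutation tests or Fisher's exact test were used. The share of a component's variance between groups or slides was tested against 100000 random orders of the 24 arrays, counting shares at least as large. The smallest p these resamples can give is 1e-05.

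The files do not pair probes with gene names, and no annotation of this array was used here. The 26 gene lists fixed before the data were examined were therefore not tested, and the results are given by probe ID. The rule for naming probes, also fixed before the data were examined, was written for genes and took those past the threshold with the largest changes and at least 5 of 6 exposed arrays on the same side of the control mean. Where fewer than 10 passed, it took the 10 with the lowest p as values that did not pass. For a file without gene names it applied to probe IDs, with at most 2 higher and 2 lower named per comparison. Between doses, only probes past the threshold were named. Probes named outside this rule are marked as chosen after their values were seen. All IDs end in _PI429335447, and this ending is left out below, so that CUST_9288 stands for the probe with that number.

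The probe numbers fall into 14393 sets of 3 consecutive numbers. Neighbouring probes of a set varied together over the arrays (median r 0.80 over 22129 pairs, with the first principal component removed), while neighbours across the border of 2 sets did not (median r 0.04 over 9554 pairs). The meaning of a set is not given in the sources used here. Means of sets were tested as an alternative where at least 2 of the 3 probes passed the filter, which gave 11716 sets.

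Where a probe was not well above background on any array of a group, its fold is given against an array floor. This floor is the lowest level among probes well above background on that array. For each array of the dimmer group, the higher of the floor and the probe's own level was taken. The mean of these was set against the mean of the brighter group. A probe can lie above the floor without being well above background, so such a fold is not a strict lower bound. The 24 arrays lay on 6 slides, numbered by scan order. Each slide held 1 control array and 1 array of 0.025 mg/L. Slide 4 held no array of 0.25 mg/L and 2 of 2.5 mg/L, and slide 6 held 2 of 0.25 mg/L and none of 2.5 mg/L. On 4 arrays the slide code in the file header differed from the slide in the file's name, and the scan times grouped them as the names did.

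The alternatives covered background correction, normalization, the filter on dim probes, slide as a block, blocks by replicate name and by letter, array weights, moderation, the threshold, the arrays in the fit, the dose scale, the deposited table, and leaving out each array in turn. The planned background alternative needed mean spot signals. It was run on the median spot signals that the files hold, with the normexp method and an offset of 50. That offset is close to the lowest 75th percentile of the processed signal on an array (51.2). Adding it shrinks the log2 changes of dim probes by itself. The smaller size of log2 changes of dim probes under normexp therefore does not by itself argue for or against those changes. This setting also used another signal and another background step, and the offset was not tested apart from them. Whether the offset accounts for calls lost in this setting was not tested. The first principal component of the 34960 probes, which held 54.3% of their variance, was put in the fit as a covariate. That choice, the sets of 3 probes and the median signals were made after the data were seen. A score on this component was scaled to a standard deviation of 1 over the 24 arrays.

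The fits without and with the component were tested on simulated data. The arrays' residuals were shuffled over the 24 arrays in 20 orders, and 200 of the 34960 probes were changed in the group of 2.5 mg/L. Against control, the fit without the component recovered 37.7% of 2-fold and 87.5% of 4-fold changes, and with the component 59.1% of 2-fold and 92.5% of 4-fold changes. With 200 probes changed at once the Benjamini-Hochberg threshold is easier to pass than with few. These shares therefore do not hold where only a few probes change. The mean number of false calls per order was 5.25 without and 9.35 with the component. In the unchanged comparison of 0.025 mg/L with control, probes passed in 1 of 20 orders without and 3 of 20 with the component.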

Results

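Transcript levels were measured in whole inland silversides, a small estuarine fish that tolerates both fresh and salt water, after 14 d in water with ibuprofen. Ibuprofen is a non-steroidal anti-inflammatory drug that inhibits the cyclooxygenases, the enzymes at the start of prostaglandin synthesis. A control group and groups at nominal 2.5, 0.25 and 0.025 mg/L were compared, with 6 arrays each, to find which transcripts respond to the drug and at which dose. Between 30191 and 35469 of the 43179 probes were well above background on an array. The 75th percentile of the processed signal lay between 51.2 and 119 intensity units per array. The mean number of probes well above background was 31343 ± 1009 (SD, n = 6) in control, 33064 ± 1715 (SD, n = 6) at 0.025 mg/L, 32461 ± 1604 (SD, n = 6) at 0.25 mg/L and 32287 ± 660 (SD, n = 6) at 2.5 mg/L. The median standard error of a log2 change against control was 0.25, and the 95% interval reached 0.52 log2 units to either side. A 2-fold change lay outside that interval for 69.4% of the 34960 tested probes at 0.025 mg/L, 71.8% at 0.25 mg/L and 76.8% at 2.5 mg/L.

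The widest difference between the samples was an on and off pattern that did not follow dose. Probe CUST_43144, the leading probe of the first principal component and chosen after its values were seen, lay between 7.38 and 8.43 on 9 arrays and at or below -1.71 on the other 15, on the log2 scale relative to the array's 75th percentile. It was high on 1 of 6 control arrays, 3 of 6 at 0.025 mg/L, 3 of 6 at 0.25 mg/L and 2 of 6 at 2.5 mg/L (Fisher's exact test over the 4 groups, p = 0.794). Sets of 3 probes with a gap of over 4 log2 units and at least 3 arrays on each side of it numbered 61, and 60 of them were high on the same 9 arrays as CUST_43144. The gaps of these 60 sets measured between 4.06 and 9.47 log2 units. High and low arrays occurred together on 4 of the 6 slides.

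**Figure D1:**
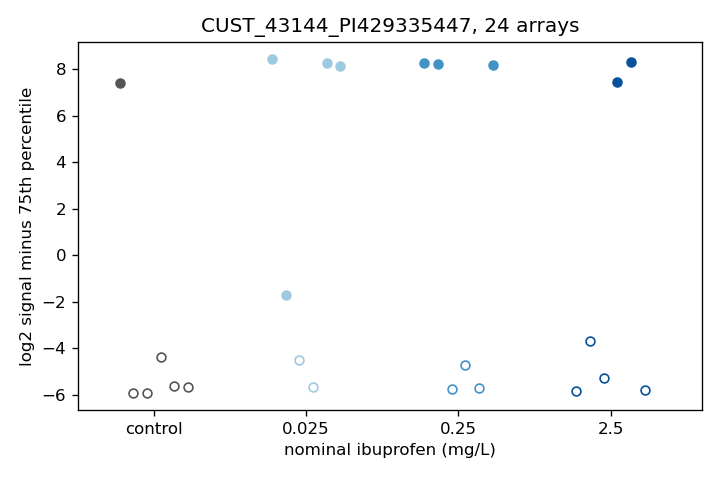
Level of probe CUST_43144 on each of the 24 arrays, by nominal ibuprofen concentration in mg/L (x axis) and as log2 signal minus the array's 75th percentile (y axis). Each circle is 1 array, filled where the probe was well above background; 9 arrays lie at 7.38 or higher, from every group, and the other 15 at -1.71 or lower.

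The first principal component held 54.3% of the variance of the tested probes and followed this pattern. Its mean score was -0.54 ± 0.57 (SD, n = 6) in control, 0.38 ± 1.23 (SD, n = 6) at 0.025 mg/L, 0.30 ± 1.16 (SD, n = 6) at 0.25 mg/L and -0.14 ± 0.87 (SD, n = 6) at 2.5 mg/L. The score did not differ from control at 0.025 mg/L (two-sided exact permutation test, p = 0.0801, adjusted over 6 comparisons 0.299), at 0.25 mg/L (p = 0.0996, adjusted 0.299) or at 2.5 mg/L (p = 0.193, adjusted 0.385). Differences between groups took 14.1% of the variance of this score (permutation p = 0.36) and differences between slides 34.7% (permutation p = 0.14). The second component held 5.26% of the variance, and 85.1% of it lay between slides (permutation p = 2.0e-05).

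At 0.025 mg/L, the lowest dose, the probes with the lowest p were lower than in control. Probe CUST_32943 had a level of -2.16 ± 0.63 (SD, n = 6) against -0.47 ± 0.62 (SD, n = 6) in control, a log2 change of -1.69 ± 0.35 (SE), or 3.22-fold lower. All 6 exposed arrays lay below the control mean, and within each of the 6 slides the exposed array lay below the control array, by log2 differences from -2.43 to -0.20. The other tested probe of its set changed by -0.48. Probe CUST_17503 was well above background on 4 of 6 control arrays and on none of the 6 exposed arrays. Set against the array floor, its level was 1.90-fold lower at 0.025 mg/L, from -3.27 ± 0.61 (SD, n = 6) in control. This is not a strict lower bound, since the probe was not well above background at -3.75 in control B4 and -4.12 in control C7. With normexp background correction on median signals, whose offset shrinks changes of dim probes, the log2 changes were -0.71 for CUST_32943 and -0.47 for CUST_17503. Neither passed the test (limma adjusted p = 0.421 for both).

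No probe passed an adjusted p of 0.05 at 0.025 mg/L in limma, and 4015 probes (11.48%) had an unadjusted p under 0.05, 1425 of them higher and 2590 lower than in control. Leaving out 1 array moved the number at an unadjusted p under 0.05 between 1730 (4.95%, without 0.025 mg/L B8) and 7521 (21.5%, without 0.025 mg/L C3). Probes with a change of at least 2-fold, whatever their p, leaned the other way, with 1347 higher and 310 lower. That lean was gone with the first principal component in the fit, with 143 higher and 176 lower. The median log2 change of all tested probes was -0.13, and -0.0004 with the component in the fit. With slide as a block in limma, 0 probes passed and 16.7% had an unadjusted p under 0.05; with the first principal component in the fit, 0 passed and the share was 4.12%, with 649 probes higher and 791 lower. Array weights changed this result: 9199 probes passed, 4091 higher and 5108 lower, and 0 passed with array weights and the component together.

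At 0.25 mg/L, the leading probes were again lower. Probe CUST_5457 had a level of 2.24 ± 0.51 (SD, n = 6) against 3.28 ± 0.12 (SD, n = 6) in control, a log2 change of -1.04 ± 0.22 (SE), or 2.06-fold lower. Probe CUST_4545 had a level of -2.89 ± 0.40 (SD, n = 6) against -1.84 ± 0.32 (SD, n = 6), a log2 change of -1.05 ± 0.23 (SE), or 2.07-fold lower. Both were below the control mean on 6 of 6 exposed arrays and below the control array on each of the 5 slides that held both groups, with log2 differences from -1.48 to -0.40 for CUST_5457 and from -1.79 to -0.48 for CUST_4545. The 3 probes of each set went the same way, from -1.04 to -0.60 in the set of CUST_5457 and from -1.22 to -0.95 in that of CUST_4545. CUST_5457 had similar values at the other doses, with log2 changes of -0.86 at 0.025 mg/L and -1.03 at 2.5 mg/L, while CUST_4545 had -0.83 at 0.025 mg/L and -0.21 at 2.5 mg/L. Neither passed the test at 0.25 mg/L (limma adjusted p = 0.561 for both), and normexp on median signals brought the log2 change of CUST_4545 to -0.33 and that of CUST_5457 to -0.77. No probe passed in limma, and 2763 probes (7.90%) had an unadjusted p under 0.05, a number that ran from 1249 (3.57%, without 0.25 mg/L A8) to 4943 (14.1%, without 0.25 mg/L B1) when 1 array was left out. Slide as a block gave 0 probes past the threshold and a share of 8.32%, and the first component in the fit gave 0 and 3.74%.

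At 2.5 mg/L, the highest dose, both higher and lower probes stood out. Probe CUST_9288 had a level of -1.79 ± 0.42 (SD, n = 6) against -3.18 ± 0.26 (SD, n = 6) in control, a log2 change of 1.39 ± 0.23 (SE), or 2.62-fold higher. Probe CUST_9283, of the neighbouring set, had a level of -0.21 ± 0.31 (SD, n = 6) against -1.24 ± 0.31 (SD, n = 6), a log2 change of 1.03 ± 0.20 (SE), or 2.04-fold higher. CUST_32943, which was also low at 0.025 mg/L, had a level of -2.37 ± 0.77 (SD, n = 6), a log2 change of -1.90 ± 0.35 (SE), or 3.74-fold lower, while the other tested probe of its set changed by -0.29. Probe CUST_23267 had a level of 2.91 ± 0.45 (SD, n = 6) against 4.19 ± 0.24 (SD, n = 6), a log2 change of -1.28 ± 0.24 (SE), or 2.43-fold lower, and the 3 probes of its set lay between -1.30 and -1.26. Each of these 4 probes was on the same side of the control mean on 6 of 6 exposed arrays and differed in the same direction on each of the 5 slides that held both groups. The log2 differences within slides ranged from 0.79 to 1.86 for CUST_9288, 0.46 to 1.54 for CUST_9283, -2.95 to -1.42 for CUST_32943 and -1.52 to -0.31 for CUST_23267.

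None of these probes passed the test at 2.5 mg/L in limma, with an adjusted p of 0.102 for CUST_9288 and 0.200 for the other 3. No probe passed, and 1404 probes (4.02%) had an unadjusted p under 0.05. That share was 1.34% with normexp on median signals, 6.33% with only the 2 groups in the fit and 7.89% with array weights. With slide as a block 0 passed and the share was 5.64%. Quantile normalization put 1 probe past the threshold, CUST_9288 with a limma adjusted p of 0.0205 and a log2 change of 1.43. With normexp on median signals its log2 change was 0.29, that of CUST_9283 0.39, that of CUST_32943 -0.55 and that of CUST_23267 -1.19. None of the 4 passed there, with a limma adjusted p of 0.99998 for CUST_9288 and CUST_9283, 0.769 for CUST_32943 and 0.122 for CUST_23267. The offset of that setting shrinks the changes of dim probes most, and CUST_23267 was the brightest of the 4. Array weights put 17 probes past the threshold.

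With the first principal component in the fit, 4 probes were higher at 2.5 mg/L than in control and passed the test. They were CUST_9288, with a log2 change of 1.46 ± 0.20 (SE, limma adjusted p = 0.00814), CUST_9283, 2.14-fold higher (limma adjusted p = 0.0337), and CUST_14965 and CUST_14967 of another set, chosen after their values were seen. CUST_14965 had a log2 change of 2.29 ± 0.36 (SE, limma adjusted p = 0.0337), or 4.88-fold, and CUST_14967 was 2.83-fold higher (limma adjusted p = 0.0337). Without the component their log2 changes were 2.12 ± 0.42 (SE) for CUST_14965 and 1.35 ± 0.32 (SE) for CUST_14967, and the limma adjusted p was 0.200 and 0.343. With normexp on median signals and no component they were 0.92 and 0.74. In the fit with the component the mean of their set of 3 probes had log2 changes of 0.59 ± 0.27 (SE) at 0.25 mg/L and 0.44 ± 0.27 (SE) at 0.025 mg/L, against 1.67 ± 0.26 (SE) at 2.5 mg/L. All 4 probes also passed with slide added to this fit. With group and replicate letter as a block (estimated correlation 0.0887) 1 probe passed, and 0 passed with normexp on median signals or when only control and 2.5 mg/L were in the fit. Without any 1 of the 24 arrays, CUST_9288 still passed, at a limma adjusted p of at most 0.0491, and the other 3 passed in 11 to 15 of the 24 fits.

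**Figure D2:**
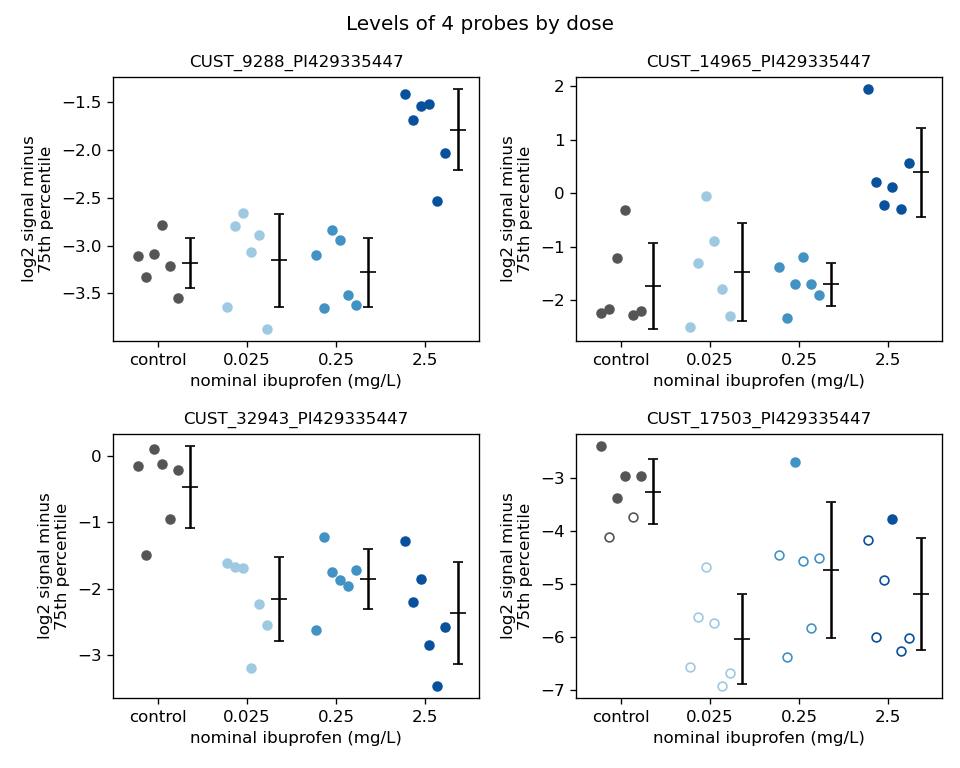
Levels of probes CUST_9288, CUST_14965, CUST_32943 and CUST_17503 by nominal ibuprofen concentration in mg/L (x axis), as log2 signal minus the array's 75th percentile (y axis). Circles are single arrays, filled where the probe was well above background, and bars are the mean ± SD of 6 arrays; CUST_9288 was higher at 2.5 mg/L alone, with means of -1.79 at 2.5 mg/L and -3.18 in control, while CUST_32943 was below the control mean at all 3 doses.

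Between doses, CUST_9288 was the single probe past the threshold. Its level at 2.5 mg/L was higher than at 0.25 mg/L, where it measured -3.28 ± 0.36 (SD, n = 6), a log2 difference of 1.49 ± 0.23 (SE), or 2.80-fold (limma adjusted p = 0.0369). It was higher on 6 of 6 arrays than the mean at 0.25 mg/L and on each of the 4 slides that held both groups, by log2 differences from 0.56 to 1.82. Its log2 change against control was -0.10 ± 0.23 (SE) at 0.25 mg/L and 0.03 ± 0.23 (SE) at 0.025 mg/L. With slide as a block the log2 difference was 1.29 and the call was lost (limma adjusted p = 0.995), and it was also lost without any 1 of 14 arrays, at a log2 difference between 1.41 and 1.52. With normexp on median signals, whose offset shrinks differences of dim probes, the difference was 0.44 (limma adjusted p = 0.724). In limma, 0 probes differed between 0.25 and 0.025 mg/L, where 642 (1.84%) had an unadjusted p under 0.05, and 0 between 2.5 and 0.025 mg/L, where 1511 (4.32%) had one. The comparison of 2.5 with 0.25 mg/L had 1916 such probes (5.48%). Leaving out 1 array moved these numbers between 579 and 1145, between 918 and 2873, and between 1188 and 2780, in the same order.

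**Figure D3:**
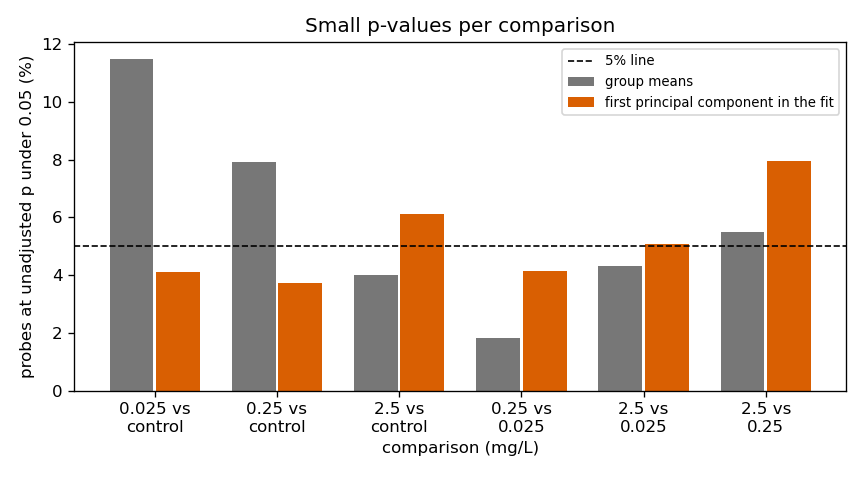
Percent of the 34960 tested probes with an unadjusted limma p under 0.05 (y axis) in the 6 comparisons between groups (x axis, concentrations in mg/L). Grey bars are the model of group means and orange bars the same model with the first principal component; the dashed line marks 5%, and at 0.025 mg/L the share went from 11.48% to 4.12% with the component in the fit.

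Over the whole dose series, the limma F test found 0 probes that differed from control at any dose, with 1750 (5.01%) at an unadjusted p under 0.05, or between 1347 and 3089 when 1 array was left out. The limma trend test on dose rank found 0 probes, with 1013 (2.90%) at an unadjusted p under 0.05. With dose in mg/L as a number, 8 probes from 4 sets passed the trend test, all with a positive slope. On this scale the slope rests mostly on 2.5 mg/L against the other groups, so it does not show a rise across the lower doses. These 8 included 3 of the 4 probes past the threshold at 2.5 mg/L with the component in the fit. Both tests draw on the arrays at 2.5 mg/L, so the overlap is no separate support. The log2 changes at 0.025 and 0.25 mg/L correlated across the tested probes, which are not independent replicates, at r = 0.858, those at 0.025 and 2.5 mg/L at r = 0.679 and those at 0.25 and 2.5 mg/L at r = 0.646. The 3 comparisons share their control arrays. In 100 simulated sets of unchanged groups the median r was 0.511, 0.531 and 0.507 in the same order, with 95% of draws between -0.26 and 0.91, -0.23 and 0.91, and -0.13 and 0.88. The covariances were 0.223, 0.129 and 0.114, against simulated means of 0.0775, 0.0890 and 0.0783. All 3 lay within the range of 95% of draws, which was -0.041 to 0.350, -0.028 to 0.394 and -0.018 to 0.330. With the controls split 3 and 3, the mean r over the 20 splits was 0.568, 0.321 and 0.278. No simulated range was made for these split values. With the first component in the fit the r values were 0.524, 0.508 and 0.433, against simulated medians of 0.504, 0.499 and 0.503.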

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

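The tests on slide, on array brightness, on ibuprofen as a switch, on single spots and on the first component without array weights were chosen after the result was seen, while those on other splits, on array weights and on single arrays were set before their values were computed.

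Among 52 sets of 6 values examined for a sample far from its group, 4 held one, and chance gives about 1 in 20 for normally spread values. That rate does not hold for the first component score and CUST_43144. Both have a high and a low level, so a single array at the other level is flagged. The number flagged is therefore not set against chance. The control sample B6 had a first component score of 0.63, while the other 5 control samples lay between -0.80 and -0.71. On CUST_43144 the same control sample had a level of 7.38, against -5.95 to -4.38 in the other 5. On CUST_5457 the control sample A5 had a level of 3.52, against 3.20 to 3.28 in the other 5. On CUST_14967 the 2.5 mg/L sample B1 had a level of 2.06, against 0.12 to 0.77 in the other 5.

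The on and off levels followed by the first component were set against 3 explanations. Slide as the sole cause would give each slide 1 level, but 4 of 6 slides held arrays of both. A smaller effect of slide remains open, with 34.7% of the variance of the component score between slides (permutation p = 0.14). The brightness of the arrays spanned 1.22 log2 units, against a gap of 9.09 log2 units on CUST_43144, too little to give the gap. Brightness still went with the pattern in part. At 0.025 mg/L the 75th percentile lay between 96.6 and 119 on high arrays and between 54.3 and 69.9 on low ones. In control, the high array B6 had 66.4, within the range of the others (51.2 to 70.7). Ibuprofen as the switch would leave controls off and exposed samples on, and 11 of 24 arrays were out of place; a smaller effect of the drug on how often the pattern occurs remains open (Fisher's exact p = 0.794 over the 4 groups). A difference between individual fish, such as sex or reproductive stage, may also give such a pattern, and it was not tested, since the labels used here give neither and the probes carry no gene names.

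The many small p-values at 0.025 mg/L (4015 probes at an unadjusted p under 0.05) went with the uneven share of the first component between the groups. With the component in the fit the percent of such probes fell from 11.48% to 4.12%. The component comes from these same arrays, so this fit also removes any response to ibuprofen that runs along it. The fall therefore does not tell such a response from another source of the component. With slide in the fit the percent of such probes rose to 16.7%. Each slide held control and 0.025 mg/L arrays in equal number, so a log2 shift shared by a slide's arrays cancels from this comparison. Slide in the fit therefore left the log2 changes as they were (median -0.126 with and without it) and could alter only their spread. The rise thus does not test slides as the source. Chance could not be excluded, since 14 of 100 splits of the 12 arrays, the real one included, gave as many (highest other split 8976). At 0.25 mg/L 19 of 100 splits gave as many as the 2763 observed (highest other 8360), and at 2.5 mg/L 16 of 100 gave as many as 1404 (highest other 3111). With array weights, 9199 probes passed at 0.025 mg/L, and 0 with the component in that fit too; 11 of 100 splits gave at least as many (highest other 11990), so chance could not be excluded there.

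Of the 4 probes higher at 2.5 mg/L with the first component in the fit, all 4 also passed with slide in the fit, which argues against slide; with the block by group and letter the count of probes past the threshold was 1. Without any 1 array, each probe kept at least 84.1% of its log2 change, although 3 of the 4 lost the call in some of these fits. The other tested probes of the same sets rose too, at an unadjusted limma p of at most 2.2e-05, which argues against faulty single spots. Of 100 splits 2, the real one included, gave as many (real count 4, highest other 5). By the share set beforehand this argues against chance for this single count. It does not exclude chance, since this fit and this comparison were chosen after the data were seen. At least 1 probe was called in 6 of the 100 splits. In the simulation with the component, probes passed in 3 of 20 orders of an unchanged comparison. A response to ibuprofen at 2.5 mg/L is a hypothesis, since the fit was chosen after the component was seen and 0 probes passed in the fit planned before.

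A count of 0 cannot be tested by other splits, since each of them reaches 0, and these splits say nothing on chance. So 100 of 100 splits were as large at 0.025 mg/L (highest other 7), 0.25 mg/L (highest other 5), 2.5 mg/L (highest other 3), between 0.25 and 0.025 mg/L (highest other 18999) and between 2.5 and 0.025 mg/L (highest other 7541). The F test (highest other 1) and the trend test (highest other 2) also had a count of 0, with the same limit for their 100 orders of the 24 arrays. For the 1 probe between 2.5 and 0.25 mg/L, 5 of 100 splits, the real one included, gave as many (highest other 4030), so chance could not be excluded. Some splits called many more probes than the real one, up to 18999, and the cause was not tested.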

How the results depend on the processing

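The fits with the first principal component, with means of sets of 3 probes and on median signals were chosen after seeing the data. The counts at 0.25 mg/L and between 0.25 and 0.025 mg/L were 0 under all 18 settings run and without any 1 array. At 0.025 mg/L the count was 0 in 17 of 18 settings and without any 1 array, and 9199 with array weights.

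At 2.5 mg/L the count of 0 became 1 higher with quantile normalization or the deposited table, 1 lower with normexp on median signals, 17 with array weights, 4 with the component, 8 with the component and slide, 4 for sets with the component, 1 for sets with the component and slide, and 0 to 2 without 1 array. Between 2.5 and 0.025 mg/L the 0 became 2 with quantile normalization, the deposited table, probes well above background on all arrays, an adjusted p of 0.10 or the component, 1 with the 75th percentile over bright probes or with the component and slide, 39 with array weights, and 0 to 7 without 1 array. Between 2.5 and 0.25 mg/L the 1 became 2 with quantile normalization, the 75th percentile over bright probes, probes bright on all arrays, the deposited table, array weights, an adjusted p of 0.10 or the component. It became 0 with normexp, slide, the replicate block, the block by group and letter, only both groups in the fit, the component with slide, and all 3 fits on sets, and 0 to 8 without 1 array. It was 0 without control B6, C7, D7 or B4, 0.025 mg/L C3 or B8, 0.25 mg/L A3, A8, B5 or C8, or 2.5 mg/L B1, B5, B8 or C6, and 8 without 2.5 mg/L D4. The F test gave 2 with quantile normalization, the 75th percentile over bright probes, bright probes, the deposited table, an adjusted p of 0.10 or the component, 9 with array weights, and 0 to 6 without 1 array. The trend test gave 8 with dose in mg/L, 2 with the component and slide, 1 for sets with the component and 1 with slide added. The cause of these changes was not tested, except that array weights are weighed above.

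The 4 probes at 2.5 mg/L with the component became 11 among probes well above background on all arrays (9 higher, 2 lower), 0 with normexp, 8 with slide, 1 with the block by group and letter, 2 with array weights, 16 at an adjusted p of 0.10 and 0 with only both groups in the fit. Without 1 array the count ran from 1 to 22, with 22 without 2.5 mg/L D4 and 21 without 2.5 mg/L D1. The r of 0.025 and 0.25 mg/L moved to 0.524 with the component and 0.568 with split controls, that of 0.025 and 2.5 mg/L to 0.487 with normexp and 0.321 with split controls, and that of 0.25 and 2.5 mg/L to 0.433 with the component and 0.278 with split controls. No named probe changed direction under any setting.

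Some groups share replicate names in the labels. Over the 7 pairs of samples with the same name the correlations of deviations from the group means ran from -0.65 to 0.43. With the first component removed they ran from -0.07 to 0.14. These 7 pairs gave no clear likeness of samples with the same name, but they cannot show what the names mark. With the replicate block the counts were 0 in all 8 comparisons and 4 at 2.5 mg/L with the component. Planned but not run were normexp on mean spot signals and the 26 gene lists with their settings, since the files used here hold neither mean signals nor gene names. Signal over background limits the dim probes, and 8219 probes were not tested.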

Other observations

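Means of sets of 3 probes, tested with the first component in the fit after the data were seen, put 4 sets past the threshold at 2.5 mg/L against control, all higher. The set of CUST_14965 to CUST_14967 had a log2 change of 1.67 ± 0.26 (SE, limma adjusted p = 0.0177), or 3.18-fold, and its mean lay above the control mean on 6 of 6 arrays. The set of CUST_9286 to CUST_9288 had a log2 change of 1.26 ± 0.22 (SE, limma adjusted p = 0.0347), also on 6 of 6 arrays, with 13 of 18 spots at 2.5 mg/L and 11 of 18 in control well above background, and CUST_9286 did not pass the filter on dim probes. The set of CUST_34564 to CUST_34566 had a smaller log2 change of 0.73 ± 0.13 (SE, limma adjusted p = 0.0347), or 1.65-fold, with all 18 spots of each group well above background. The set of CUST_22702 to CUST_22704 was well above background on 11 of 18 spots at 2.5 mg/L and on 0 of 18 spots in control (limma adjusted p = 0.0347), and its mean lay above the control mean on 5 of 6 arrays. With slide added to the fit, 1 set passed. Without the component the adjusted p of these 4 sets in limma lay between 0.312 and 0.319.

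CUST_9283 and CUST_9288 lie in neighbouring sets of the probe numbering and both were higher at 2.5 mg/L. CUST_14966, which lies between CUST_14965 and CUST_14967, had a log2 change of 1.22 with the component in the fit. What these probes measure is not given in the sources used here.

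One set stood apart from the on and off pattern. The set of CUST_7708 to CUST_7710 had a gap of 5.37 log2 units and was high on 6 of 24 arrays: 2 control arrays, 1 at 0.025 mg/L, 1 at 0.25 mg/L and 2 at 2.5 mg/L. High and low arrays of this set occurred together on 5 of the 6 slides.

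Array weights at 0.025 mg/L were uneven, a result seen after the fits were run. The 3 arrays with CUST_43144 high had weights between 1.06 and 2.09, and the 3 with it low had weights between 0.410 and 0.480.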
